A study of Mus musculus with 18 samples.

How the data were processed

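RNA was measured in regulatory T cells (Tregs) sorted from the spleens of male Foxp3IRES-GFP mice, a reporter strain in which cells expressing the Treg transcription factor Foxp3 carry green fluorescent protein. Mice received a retro-orbital intravenous injection of PBS or of IL2_JES6, a complex of interleukin-2 with the antibody clone JES6-1, and spleens were taken 1 to 128 h later. Per the labels, 1000 cells per library were sorted as negative for propidium iodide, CD19, CD8, TER119 and GR1 and positive for TCRB, CD4 and high CD25. Libraries followed the Smart-seq2 protocol, with oligo-dT priming, limited PCR and Nextera XT fragmentation, and the protocol as given names no molecular identifiers. The series also covers the immunocytokines F10 and F511, which were not analysed here.

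The deposited table holds counts, whole numbers of reads per gene symbol with no normalization, for 55011 symbols in 18 libraries. The authors' processing notes name STAR 2.7.3a, featureCounts and the genome build mm10. The annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so it is not known how reads shared by paralogs or by genes on opposite strands at the same place were counted. Gene coordinates were taken from GENCODE M21 on GRCm38, which held 13646 of the 13884 symbols tested.

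Group, time and replicate number came from the labels. The injected groups had 2 libraries each at 1, 4, 8, 16, 24, 64 and 128 h and 1 library at 2 h, and PBS had 2 libraries at 2 h and 1 at 128 h. The 3 PBS libraries served together as the control, since PBS was harvested at no other time. Beyond these labels nothing states that replicates came from separate mice, so p-values measure the spread between these samples. Replicate numbers were tested as pairs between the 7 groups holding replicates 1 and 2 of injected or PBS libraries. The 21 correlations of the replicate difference lay between -0.15 and 0.27, and 8 exceeded 0.1. Libraries were treated as unpaired, though these correlations over many genes do not exclude a shared difference in some. The cycling-cell genes Mki67 and Birc5, looked at afterwards, were higher in replicate 1 in all 7 groups. At 1 h and 2 h only replicate 1 entered the fit, so comparisons of these times also differ in replicate number. A replicate block is among the alternatives.

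The second 1 h library held 213 counts in 115 genes, and 24.4% of them (95% Wilson interval 19.1 to 30.6) came from Gm10800, a predicted gene. It was left out by a minimum of 1000 counts, a rule set after the data were seen, which departs from the planned fit of all 18 libraries. The planned fit is kept as an alternative. The other 17 libraries held 1483975 to 5779645 counts.

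Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. A gene was tested if at least 2 of the 17 libraries held 10 or more counts after scaling to the median library size. The 13884 genes passing held 99.6% of counts. Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM normalization, robust dispersion estimates and quasi-likelihood F tests, in a single fit with a coefficient for each injected time and for PBS. PBS at 128 h against PBS at 2 h was tested in a second fit of the same 17 libraries with PBS split by harvest time. The biological coefficient of variation of the first fit was 0.223. A lone library, at 1 h, at 2 h, in PBS at 128 h or where leaving 1 out leaves 1, is assumed to vary like the other groups. Values of p were adjusted by the Benjamini-Hochberg method over all genes within a comparison, and an adjusted p under 0.05 counts as a call. Log2 changes are fitted values, given with an approximate standard error (SE) after the sign ±. This SE is the absolute log2 change divided by the square root of its F statistic. CPM are read counts scaled to the TMM library size on the usual CPM scale, given with the standard deviation (SD) between libraries. Tests covered each of the 8 times against PBS, any time against PBS, 24 h against 1 h, 128 h against 24 h, and PBS at 128 h against PBS at 2 h.

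The 30 gene lists named 771 members. Some genes are in several lists, so the results of such lists are not independent. Each list with at least 5 tested members was tested by camera in limma 3.58.1, which asks whether its genes moved more than the other genes, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Its p-values were adjusted over all 270 tests of 27 lists in 10 comparisons, and again with the correlation estimated from the data. Where a list is followed through the alternatives, its mean difference is given in these log2 CPM, which differs slightly from the mean of fitted log2 changes given elsewhere. Members called are counted over all genes and adjusted over the list alone.

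Genes were named by a fixed rule in 3 parts. The first part is a panel of 22 genes. The second takes the 6 highest and 4 lowest log2 changes of each comparison among called genes with a mean of at least 10 CPM and no overlap between groups, leaving out predicted genes, clones, pseudogenes and antigen receptor segments. The third takes up to 4 called members of each list, those with the largest absolute log2 change, in the comparison with PBS where most of its members were called. The largest rises and falls described below are those among genes that pass the second part of this rule.

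Each library's depth limits what it can show: where a group holds 0 counts, the ratio is computed against 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% counting interval. Intervals and these floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The procedure was tested on simulated data with 200 changed genes: at 4 h it recovered 39.4% of genes changed by 1 log2 unit and 65.3% of those changed by 2, with 12 calls among unchanged genes. At 1 h these shares were 21.6% and 56.1%.

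Alternatives were DESeq2 1.42.0, RLE normalization, no low count filter, a filter at 50 scaled counts, the compared groups alone, a replicate block, all libraries thinned to 1483975 counts, a minimum 2-fold change, and each library left out in turn. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.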

Results

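RNA was sequenced from splenic Tregs of mice injected with IL2_JES6, the complex of interleukin-2 (IL-2) with antibody JES6-1, or with PBS. IL-2 is the cytokine that Tregs depend on through their high CD25, the alpha chain of its receptor. Cells were also sorted on high CD25, the product of Il2ra, a gene that changed after injection. Whether the injection altered which cells passed the sort was not tested. The labels set the question as how Tregs of injected mice compare with those of PBS mice from 1 to 128 h after injection. After 1 failed library was left out, 14 libraries from injected mice and 3 from PBS mice were compared: 1 library each at 1 h and 2 h, 2 each at 4, 8, 16, 24, 64 and 128 h, and 3 from PBS mice. PBS values are means over these 3 libraries throughout, and values at 1 h and 2 h have no replicate.

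Library totals ran from 4167473 to 5779645 counts, apart from 1483975 in 8 h replicate 2. That library stood apart from the rest, with 15716 genes detected and 0.366% of counts from mitochondrial genes (95% Wilson interval 0.357 to 0.376), against 0.768% to 1.15% in the other 16 libraries. Its log2 CPM had a Spearman correlation of 0.943 with 8 h replicate 1 across the 13884 genes tested, which are not independent replicates. The other pairs within a group had 0.968 to 0.977. The first principal component of the 2000 most variable genes held 29.0% of the variance, with the 64 h libraries at -58.9 and -48.6 and the PBS libraries between 12.2 and 26.4. The injected libraries of 1 h to 8 h lay between 15.6 and 34.6 on it, so it did not part them from PBS. The second component held 15.0%, and 8 h replicate 2 lay at 59.7 on it, against 12.6 for the next highest library. On this second component the PBS libraries lay between -30.4 and -28.1, below every injected library, the lowest of which stood at -13.0.

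Of 13884 genes tested, 4021 differed from PBS when all 8 times were tested together. The number of genes called was 278 at 1 h, 784 at 2 h, 2184 at 4 h, 2698 at 8 h, 1789 at 16 h, 1813 at 24 h, 3541 at 64 h and 1122 at 128 h. Among the 4021 genes the largest absolute log2 change lay at 64 h for 879 higher and 466 lower genes and at 8 h for 531 higher and 379 lower genes. All 8 h numbers here include 8 h replicate 2, which stood apart. The counts at other times come from the same fit, with a shared estimate of spread. Those at 1 h and 128 h were higher without either 8 h library, as given below. The times of largest change were not computed without that library. Among the genes described below, Il2ra lies on chromosome 2 (11642807 to 11693193) and Cish on chromosome 9 (107296026 to 107302784). Foxp3 lies on chromosome X (7573644 to 7595245), Tcf7 on chromosome 11 (52252371 to 52283014) and Gzmb on chromosome 14 (56258838 to 56262260), all at GRCm38 positions.

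**Figure D1:**
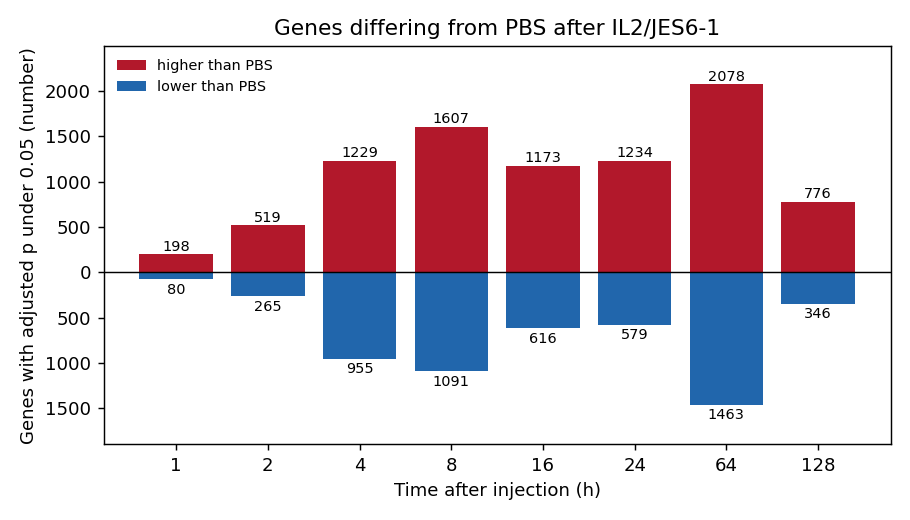
Number of genes with an adjusted p under 0.05 against PBS (vertical axis) at each time after IL2_JES6 injection in hours (horizontal axis), with bars above 0 for genes higher than PBS and bars below 0 for genes lower than PBS. The tallest bars stand at 64 h, with 2078 genes higher and 1463 lower.

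PBS mice taken at 128 h and at 2 h were compared to see whether the control changed with harvest time. In simulated data this comparison recovered 11.5% of genes changed by 1 log2 unit and 53.5% of those changed by 2. Few calls therefore do not show that the control stayed the same. PBS was not harvested at other times, so an effect of harvest time there was not measured. Cirbp, an RNA-binding protein induced by cold, was higher at 128 h (188 CPM in 1 library against 42.7 ± 9.39 in 2, log2 change 2.14 ± 0.30, adjusted p = 0.0185). Stip1, a co-chaperone of heat shock proteins, was lower (120 against 335 ± 26.2 CPM, log2 change -1.47 ± 0.23, adjusted p = 0.0403). These 2 genes were the only ones that edgeR called, with 735 genes at an unadjusted p under 0.05, and DESeq2 called 19. The count fell to 0 without either 2 h PBS library or either 24 h library and was 1 without either 4 h or 16 h library. Cirbp then had adjusted p of 0.0515 to 0.278 where its call ended, and Stip1 0.0502 to 0.278. In the planned fit of all 18 libraries, with the failed one, Stip1 had 0.108. The count reached 11 without either 8 h library, 5 without 128 h replicate 1 and 4 without 128 h replicate 2.

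At 1 h some genes listed as IL-2/STAT5 targets, Cish and Il2ra among them, were already higher than in PBS. Cish, an inhibitor of cytokine receptor signalling, stood at 1145 CPM against 263 ± 17.4 (log2 change 2.12 ± 0.19, adjusted p = 1.65e-06), and Il2ra, which encodes CD25, at 2749 against 797 ± 51.2 CPM (1.79 ± 0.16, adjusted p = 1.65e-06). The feedback inhibitors Socs1 and Socs2 rose by 2.04 ± 0.26 and 1.83 ± 0.15, the growth regulator Myc by 1.96 ± 0.32 and the kinase Pim1 by 1.10 ± 0.18 on the log2 scale. Il2rb, the beta chain of the IL-2 receptor, rose by 0.91 ± 0.17. With all 18 libraries, which include the failed one at 1 h, the calls of Il2ra (log2 change 1.35, adjusted p = 0.104) and Il2rb (0.45, adjusted p = 0.837) ended. In the 17 libraries Foxp3 at 0.45 ± 0.20 and Bcl2, an inhibitor of cell death, at 0.98 ± 0.37 were not called. The largest rises were those of Lif, a cytokine of the interleukin-6 family (64.2 against 2.81 ± 0.65 CPM, log2 change 4.49 ± 0.35), the transcription factor Myb (3.63 ± 0.31), and Hbegf, an epidermal growth factor family ligand (3.43 ± 0.41). They were followed by the adhesion molecule Jaml (3.02 ± 0.45), the potassium channel Kcnk5 (2.86 ± 0.31) and lymphotoxin alpha, Lta (2.79 ± 0.25). Tbc1d31 (-3.28 ± 0.74) and the gut-homing receptor Ccr9 (-3.22 ± 0.60) fell most. Next came the potassium channel partner Kcnip2 (-3.08 ± 0.62) and Plxdc1 (-2.63 ± 0.62, adjusted p = 0.0274, 0.0622 without the 128 h PBS library and 0.133 with thinned libraries). Tbc1d31 had 0.0858 with the compared groups alone and stood at -2.65 without 2 h PBS replicate 2. Hbegf stood at 4.06 without the 128 h PBS library and Jaml at 3.85 without 2 h PBS replicate 1. Tcf7, a transcription factor of resting T cells, fell from 310 ± 38.0 to 75.6 CPM (log2 change -2.04 ± 0.26, adjusted p = 0.00013).

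Of the 30 IL-2/STAT5 targets tested, 12 rose at 1 h, and 15 did so adjusted over the list alone (camera adjusted p = 1.6e-12, adjusted p = 0.0595 with an estimated correlation). In the list of cytokine signalling brakes 7 of 17 genes rose, 9 adjusted over the list alone (adjusted p = 1.06e-07, adjusted p = 0.0507 with an estimated correlation). The Treg core list had 7 of 25 genes higher, 8 adjusted over the list alone (adjusted p = 5.63e-08, adjusted p = 0.0594 with an estimated correlation). These lists overlap: Cish, Socs1 and Socs2 are listed both as IL-2/STAT5 targets and as brakes, and Il2ra and Socs2 both as targets and as Treg core. Ribosome biogenesis genes rose in 13 of 38 cases, 26 adjusted over the list alone (adjusted p = 3.42e-20, adjusted p = 0.0594 with an estimated correlation). The type I interferon response list, genes induced by antiviral cytokines, had a mean log2 change of 0.61 with 5 of 42 genes called, 18 adjusted over the list alone (adjusted p = 1.18e-10, adjusted p = 0.215 with an estimated correlation). Without the 128 h PBS library 3 were called, and 2 without 2 h PBS replicate 2. With all 18 libraries the Treg core list was lower at 1 h (adjusted p = 0.0277) and the other 4 lists were not called (adjusted p of 0.422 to 0.851). The total was 198 genes higher and 80 lower, with 1619 genes at an unadjusted p under 0.05, and it was 508 without 8 h replicate 1 and 509 without 8 h replicate 2. DESeq2 called 458, and 457 were called without a low count filter.

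At 2 h Cish, Il2ra and Myc were still high, and most ribosome biogenesis genes tested had risen. Cish stood at 1180 CPM (log2 change 2.17 ± 0.19), Il2ra at 2996 (1.91 ± 0.16) and Myc at 799 (1.99 ± 0.32). Foxp3 rose to 2311 from 1154 ± 166 CPM (1.00 ± 0.20, adjusted p = 0.00348, and 0.217 with all 18 libraries). Il7r, the receptor for the survival cytokine interleukin-7, fell to 71.2 from 309 ± 39.0 CPM (-2.12 ± 0.35, adjusted p = 0.00077), and Tcf7 fell by 1.97 ± 0.26. Of 38 ribosome biogenesis genes 32 rose, 34 adjusted over the list alone, with a mean log2 change of 1.29 (camera adjusted p = 3.69e-34, adjusted p = 0.0373 with an estimated correlation).

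The largest rises at 2 h were those of Lif (4.31 ± 0.36), Myb (3.62 ± 0.31), Kcnk5 (3.45 ± 0.30), Hbegf (3.33 ± 0.41, and 3.96 without the 128 h PBS library), the DNA-processing helicase Dna2 (3.29 ± 0.37) and Lta (2.96 ± 0.25). The largest falls were those of Naip2, an inflammasome sensor (-2.65 ± 0.61), Scrn3 (-2.61 ± 0.56), Padi2 (-2.53 ± 0.63) and Arl5c (-2.51 ± 0.29), with adjusted p of 0.0505 for Naip2 and 0.0908 for Padi2 in thinned libraries. Among the 17 cytokine signalling brakes 7 rose and 2 fell, 9 and 3 adjusted over the list alone (adjusted p = 0.00044, adjusted p = 0.0898 with an estimated correlation). They included Spry1, an inhibitor of growth factor signalling (2.31 ± 0.35), and Rgs1, an inhibitor of chemokine receptor signalling (2.15 ± 0.19). Rgs16, of the same family, fell (-2.22 ± 0.59, adjusted p = 0.0313), with adjusted p = 0.0654 without the 128 h PBS library, 0.0706 without 2 h PBS replicate 2 and 0.164 with thinned libraries. In the amino acid and ATF4 list, genes of amino acid uptake and synthesis, 13 of 28 rose and 1 fell, 17 and 1 adjusted over the list alone (adjusted p = 5.86e-10, adjusted p = 0.16 with an estimated correlation). Slc7a5, a leucine transporter, rose to 16.0 from 3.87 ± 1.24 CPM (2.05 ± 0.46, adjusted p = 0.0107). That call ended with thinned libraries (1.68, adjusted p = 0.137) and with the compared groups alone (adjusted p = 0.0506). The total was 519 genes higher and 265 lower.

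At 4 h nearly all ribosome biogenesis genes and most amino acid genes were high. Of 38 ribosome biogenesis genes 37 rose, 37 adjusted over the list alone, with a mean log2 change of 1.45 (camera adjusted p = 7.13e-34, adjusted p = 0.0373 with an estimated correlation). They included the nucleolar genes Gar1 (2.27 ± 0.42), Rrp12 (2.23 ± 0.25), Mrto4 (2.14 ± 0.18) and Mybbp1a (818 ± 42.9 in 2 libraries against 199 ± 21.4 CPM, 2.04 ± 0.13). In the amino acid and ATF4 list 23 of 28 genes rose and 1 fell, 24 and 1 adjusted over the list alone, with a mean of 1.62 (adjusted p = 2.84e-17, adjusted p = 0.0898 with an estimated correlation). The neutral amino acid transporter Slc1a4 rose to 31.0 ± 23.6 from 0.413 ± 0.452 CPM (6.12 ± 1.07), Pycr1, an enzyme of proline synthesis, by 3.81 ± 0.70, asparagine synthetase, Asns, by 3.76 ± 0.72 and Slc7a5 by 2.52 ± 0.39. Slc1a4 stood at 6.74 and 5.01 without 4 h replicates 1 and 2. Without 2 h PBS replicate 1 it held 2 counts in PBS, a ratio of 171 (95% counting interval 46.9 to 1419).

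Among Treg core genes 12 of 25 rose and 3 fell at 4 h, 13 and 4 adjusted over the list alone (adjusted p = 7.69e-05, adjusted p = 0.0898 with an estimated correlation). Ecm1 (2.41 ± 0.33), the orphan receptor Gpr83 (2.12 ± 0.22) and Lrrc32, which presents latent TGF-beta on the Treg surface (2075 ± 30.7 against 487 ± 89.1 CPM, 2.09 ± 0.15), rose most beside Socs2 (1.93 ± 0.13). Gcsh, of the glycine cleavage system, rose by 3.68 ± 0.22 and the potassium channel Kcnj15 by 4.74 ± 0.59, beside Lif (4.57 ± 0.32) and Myb (3.62 ± 0.28). The largest falls were those of Ccr9 (-4.22 ± 0.49), the sialyltransferase St8sia6 (-3.63 ± 0.60, with 5.67 and 0.678 CPM in 4 h replicates 1 and 2), the nucleoside transporter Slc28a2b (-3.26 ± 0.22) and Arrdc4 (-3.18 ± 0.60). Il7r fell by 2.61 ± 0.27 and Tcf7 by 1.93 ± 0.20. Without 4 h replicates 1 and 2 Ccr9 stood at -5.45 and -3.56, and St8sia6 at -2.80 without replicate 2. Without replicate 1 St8sia6 held 3 counts at 4 h, a PBS to injected ratio of 58.0 (95% counting interval 19.8 to 282.1). Without the 128 h PBS library Arrdc4 stood at -2.53 and Kcnj15 held 3 counts in PBS, a ratio of 102 (95% counting interval 34.5 to 498.5).

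The T cell receptor complex list had 1 of 21 genes higher and 9 lower at 4 h, 1 and 10 adjusted over the list alone (adjusted p = 0.0208, adjusted p = 0.379 with an estimated correlation), with 4 lower without either 4 h library. The call was lost without 2 h PBS replicate 2 (adjusted p = 0.0536) and with all 18 libraries (0.667). The glycoprotein Cd52 (-0.97 ± 0.16), the coreceptor Cd4 (368 ± 5.31 against 702 ± 6.16 CPM, -0.93 ± 0.13) and Cd5 (-0.89 ± 0.14) fell, and the adhesion molecule Cd2 rose (0.88 ± 0.14). In the immediate early list, rapidly induced transcription regulators, 5 of 26 genes rose and 4 fell, 5 and 4 adjusted over the list alone, and the list was not called (adjusted p = 0.988). Nr4a3 rose (1.78 ± 0.28) and the antiproliferative gene Btg2 fell (-1.82 ± 0.30), while the rises of Fos (2.31 ± 0.49, adjusted p = 0.0027) and Jun (1.65 ± 0.51, adjusted p = 0.0451) ended without 4 h replicate 2, with log2 changes of 1.66 and 1.03 and adjusted p of 0.0961 and 0.372. That library also left 1 rise in this list, and without 4 h replicate 1 the list had 1 fall. Jun had adjusted p of 0.0595 and 0.0571 without 8 h replicates 1 and 2, 0.128 without the 128 h PBS library, 0.119 without 2 h PBS replicate 1 and 0.0649 with all 18 libraries.

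The list of G2/M genes, which act in mitosis, was lower at 4 h, with 6 of 40 called and 11 adjusted over the list alone (mean log2 change -1.80, adjusted p = 8e-08, adjusted p = 0.422 with an estimated correlation). Without 4 h replicate 2 only 3 were called. Mki67, a marker of cycling cells, stood at 4.65 ± 3.06 against 27.9 ± 4.37 CPM (-2.58 ± 0.64, adjusted p = 0.015, 0.144 without 4 h replicate 2 and 0.139 without a low count filter, and -3.48 without 4 h replicate 1). Gzmb, the cytotoxic protease granzyme B, rose to 203 ± 68.6 CPM (2.47 ± 0.53, adjusted p = 0.0098, 0.0633 without 4 h replicate 1 and 0.0581 without a low count filter). The total at 4 h was 1229 genes higher and 955 lower, and it was 1156 without 4 h replicate 1 and 1249 without 4 h replicate 2. With a minimum 2-fold change the balance turned, with 500 higher and 527 lower.

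At 8 h most genes tested of the unfolded protein response and of oxidative phosphorylation rose. Of 26 unfolded protein response genes 16 rose, 17 adjusted over the list alone (camera adjusted p = 1.33e-08, adjusted p = 0.0898 with an estimated correlation). The chaperone-like genes Pdia4 (795 ± 26.3 against 200 ± 19.3 CPM, 1.99 ± 0.12), Creld2 (1.90 ± 0.20) and Sdf2l1 (1.85 ± 0.25) rose with Xbp1, the transcription factor of this response (1.95 ± 0.16). Of 32 oxidative phosphorylation genes 26 rose, 30 adjusted over the list alone (adjusted p = 1.25e-16, adjusted p = 0.118 with an estimated correlation), among them Atp5d (1.52 ± 0.18), Cyc1 (1.38 ± 0.18), Uqcrq (1.38 ± 0.20) and cytochrome c, Cycs (1.28 ± 0.22). The first 3 were higher in 8 h replicate 2, which stood apart, at 925, 492 and 317 CPM against 519, 292 and 160 in replicate 1. Without that library 25 of the 32 genes were called, with Atp5d at 1.06, Cyc1 at 0.98, Uqcrq at 0.84 and Cycs at 1.10. In the glycolysis list 11 of 22 genes rose and 2 fell, 12 and 2 adjusted over the list alone (adjusted p = 0.00163, adjusted p = 0.266 with an estimated correlation), with 7 higher without 8 h replicate 2. The enzymes Eno1 (1.97 ± 0.17), Gapdh (1.33 ± 0.16) and Tpi1 (1.13 ± 0.22) rose, and the glucose transporter Slc2a3 fell (-1.32 ± 0.19).

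Transglutaminase 2, Tgm2, rose to 132 ± 41.3 from 3.22 ± 1.82 CPM at 8 h (5.33 ± 0.51, adjusted p = 1.47e-05). The other largest rises were those of Lif (4.50 ± 0.33), Gcsh (4.14 ± 0.22), Hbegf (4.03 ± 0.37, and 4.65 without the 128 h PBS library), the ephrin Efna5 (3.57 ± 0.48) and Plac8 (3.55 ± 0.37). The largest falls were those of the chemokine receptor Ccr3 (-3.99 ± 0.99, adjusted p = 0.0091, and 0.0667 without 8 h replicate 2), the guanylate cyclase subunit Gucy1a1 (-3.69 ± 0.79), Btbd11 (-3.54 ± 0.70) and Ccr9 (-3.50 ± 0.49). Ccr3, Gucy1a1 and Btbd11 had 0 counts in 8 h replicate 2 and 2.12, 2.54 and 2.54 CPM in replicate 1. Without replicate 1 they were lower by at least 10.67-fold, 10.04-fold and 9.37-fold, against 3 counts where 0 were seen. Of 24 resting or naive T cell genes 14 fell and 1 rose, 15 and 1 adjusted over the list alone (adjusted p = 6.35e-06, adjusted p = 0.325 with an estimated correlation). In the BCL2 family, regulators of cell death, 2 of 17 genes rose and 2 fell, 3 and 2 adjusted over the list alone, and the list was not called (adjusted p = 0.93). Bax and Bid, which promote cell death, rose (1.74 ± 0.21 and 0.84 ± 0.24), Bid with an adjusted p of 0.0185, 0.211 without 8 h replicate 2 and 0.0827 without 2 h PBS replicate 1. Bcl2l11, which does so too, fell (-1.67 ± 0.36, adjusted p = 0.0023, and 0.0589 without 8 h replicate 1). Mcl1, which opposes cell death, fell (-0.55 ± 0.18, adjusted p = 0.0361), with adjusted p of 0.235 without 8 h replicate 2, 0.0511 without 128 h replicate 2 and 0.106 and 0.0831 without 2 h PBS replicates 1 and 2. Its call also ended with all 18 libraries (0.083), with the compared groups alone (0.122) and without a low count filter (0.0627).

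In 8 h replicate 2, which stood apart, ribosomal protein genes were high. The list had 16 of 44 genes higher at 8 h, 21 adjusted over the list alone (adjusted p = 1.05e-05, adjusted p = 0.662 with an estimated correlation). The mean difference of the list in log2 CPM was 0.43, and -0.04 without that library (adjusted p = 0.638), with 1 gene called. The number was 40 without 8 h replicate 1, 7 without the 128 h PBS library and 6 and 4 without 2 h PBS replicates 1 and 2. Rpl10a stood at 1.18 ± 0.24, and at 0.39 without 8 h replicate 2, while Rpl7a (0.92 ± 0.20), Rpl27 (1.00 ± 0.28) and Rpl28 (0.96 ± 0.30) had adjusted p of 0.114, 0.751 and 0.923 without 8 h replicate 2, Rpl27 then at 0.0911 and Rpl28 at 0.0387. Without 8 h replicate 1 Rpl27 stood at 1.58 and Rpl28 at 1.55. Without 2 h PBS replicate 1 the adjusted p were 0.0569 for Rpl27 and 0.0901 for Rpl28, and without 2 h PBS replicate 2 they were 0.0604 for Rpl27 and 0.088 for Rpl28. Without 128 h PBS replicate 1 Rpl28 had 0.058. The list of mitochondrial transcripts had a mean log2 change of -0.39 (adjusted p = 0.0659), and 7 of its 10 genes were lower without 8 h replicate 1.

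DNA replication genes rose at 8 h in 11 of 38 cases, 14 adjusted over the list alone (adjusted p = 2.02e-05, adjusted p = 0.49 with an estimated correlation), and 7 higher without 8 h replicate 2. Mcm5, a subunit of the replicative helicase, rose to 311 ± 109 from 77.3 ± 16.1 CPM (1.99 ± 0.29, adjusted p = 0.00019). G2/M genes were lower in 8 of 40 cases, 8 adjusted over the list alone (mean -1.79, adjusted p = 0.00031, adjusted p = 0.636 with an estimated correlation), with 4 called without 8 h replicate 2, 5 without the 128 h PBS library or 2 h PBS replicate 1, and 0 without 8 h replicate 1. Foxp3 stood at 0.75 ± 0.16 (adjusted p = 0.0026), and at 0.39 with adjusted p = 0.0621 without 8 h replicate 2, and its adjusted p was 0.131 with all 18 libraries. The total at 8 h was 1607 genes higher and 1091 lower, and it was 1710 without 8 h replicate 2 and 1705 with the compared groups alone.

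At 16 h most interferon gamma response genes and most DNA replication genes tested rose. In the interferon gamma response list, genes induced by that T cell cytokine, 22 of 31 rose, 25 adjusted over the list alone (mean log2 change 0.88, camera adjusted p = 2.13e-15, adjusted p = 0.0518 with an estimated correlation). Of 19 genes of antigen presentation by class I 14 rose, 14 adjusted over the list alone (adjusted p = 3.01e-08, adjusted p = 0.149 with an estimated correlation). The immunoproteasome genes Psmb8 (2054 ± 11.2 against 697 ± 37.6 CPM, 1.56 ± 0.13), Psme2 (1.31 ± 0.16) and Psmb10 (1.12 ± 0.19) rose with the chaperone calreticulin, Calr (1.32 ± 0.13). Psmb8 and Psmb10 are among the genes that this list shares with the interferon gamma response list. Of 38 DNA replication genes 30 rose, 34 adjusted over the list alone (adjusted p = 6.62e-22, adjusted p = 0.147 with an estimated correlation).

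Tgm2 stood at 343 ± 15.7 CPM at 16 h (6.73 ± 0.50), the iron-binding protein gene Ltf at 34.0 ± 10.5 CPM (5.10 ± 0.61), and Ifitm3, which restricts viral entry, at 136 ± 41.5 against 6.23 ± 2.74 CPM (4.43 ± 0.35). Lif (4.81 ± 0.32), Plac8 (4.08 ± 0.36) and Gcsh (3.74 ± 0.22) were also among the largest rises. The largest falls were those of the proton pump subunit Atp6v0d2 (-4.26 ± 0.87), Bcl6, a repressor that directs follicular T cells (-3.44 ± 0.50), the sulfotransferase Chst2 (-2.86 ± 0.64) and Ccr3 (-2.80 ± 0.84, adjusted p = 0.0369). Without 16 h replicate 2 the adjusted p were 0.0586 for Atp6v0d2, 0.0878 for Chst2 and 0.19 for Ccr3, with Atp6v0d2 at -3.36 and Ccr3 at -1.79. For Ccr3 they lay between 0.0522 and 0.0562 without either 4 h or 24 h library and between 0.0645 and 0.0944 without any PBS library, and DESeq2 gave 0.0518. Its 16 h libraries held 7.03 and 0.196 CPM, and without replicate 1 it held 1 count at 16 h, a PBS to injected ratio of 123.9 (95% counting interval 22.1 to 4907). Without 16 h replicate 1 Atp6v0d2 held 1 count at 16 h, a PBS to injected ratio of 90.1 (95% counting interval 16.05 to 3571). Ltf stood at 6.44 without 2 h PBS replicate 1. Class I genes called were 9 without 16 h replicate 1 or 2 h PBS replicate 1 and 8 without 16 h replicate 2. The total was 1173 genes higher and 616 lower, and it was 912 without 16 h replicate 1 and 861 without 16 h replicate 2.

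At 24 h all 38 DNA replication genes tested were higher than PBS, and 38 were so adjusted over the list alone (mean log2 change 2.46, camera adjusted p = 1.03e-30, adjusted p = 0.096 with an estimated correlation). The replication licensing gene Cdc6 rose to 94.1 ± 25.6 from 2.83 ± 3.11 CPM (5.08 ± 0.75), Chaf1a by 4.29 ± 0.58, Mcm10 by 4.11 ± 0.86 (adjusted p = 0.0724 without a low count filter), Gins1 by 3.89 ± 0.75 and Mcm5 by 3.06 ± 0.29. Without the 128 h PBS library Cdc6 stood at 6.46, Chaf1a at 4.91 and Mcm10 at 4.85. In the interferon gamma response list 25 of 31 genes rose, 26 adjusted over the list alone (adjusted p = 1.72e-17, adjusted p = 0.0507 with an estimated correlation). The GTPases Gbp2 (1188 ± 101 against 224 ± 35.0 CPM, 2.41 ± 0.17), Iigp1 (2.11 ± 0.21) and Tgtp1 (1.78 ± 0.19) rose with Socs1 (2.30 ± 0.22).

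Tgm2 reached 617 ± 91.5 CPM at 24 h (7.58 ± 0.51, adjusted p = 1.27e-06), and Lif rose by 5.29 ± 0.32, Ifitm3 by 4.91 ± 0.35, Plac8 by 4.63 ± 0.36 and the repair helicase Brip1 by 4.61 ± 0.89. Bcl6 fell by 3.71 ± 0.50 and Rgs16 by 3.01 ± 0.48. Atp6v0d2 (-3.23 ± 0.77) stood at -2.38 with adjusted p = 0.112 without 24 h replicate 2 and held 3.37 and 0.365 CPM in 24 h replicates 1 and 2, and the cholesterol exporter Abca1 (-2.98 ± 0.61) had 0.0753 without 24 h replicate 1. Without 24 h replicate 1 Atp6v0d2 held 2 counts at 24 h, a PBS to injected ratio of 48.4 (95% counting interval 13.3 to 401.1). Brip1 stood at 3.98 without 24 h replicate 1 and 5.44 without the 128 h PBS library, Rgs16 at -3.71 without 24 h replicate 1 and Bcl6 at -4.54 without 24 h replicate 2. G2/M genes rose in 16 of 40 cases, 28 adjusted over the list alone (adjusted p = 9.07e-11, adjusted p = 0.325 with an estimated correlation), and the number was 4 without 24 h replicate 1, 9 without 2 h PBS replicate 1 and 7 without 2 h PBS replicate 2. Mki67 stood at 85.9 ± 22.5 CPM (1.62 ± 0.48, adjusted p = 0.0426), a call that ended without any of the 24 h, 8 h or PBS libraries (adjusted p 0.0671 to 0.265). It also ended with DESeq2 (0.0576), with all 18 libraries (0.0634) and without a low count filter (0.267). The total was 1234 genes higher and 579 lower, and it was 681 without 24 h replicate 1 and 1081 without 24 h replicate 2.

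**Figure D2:**
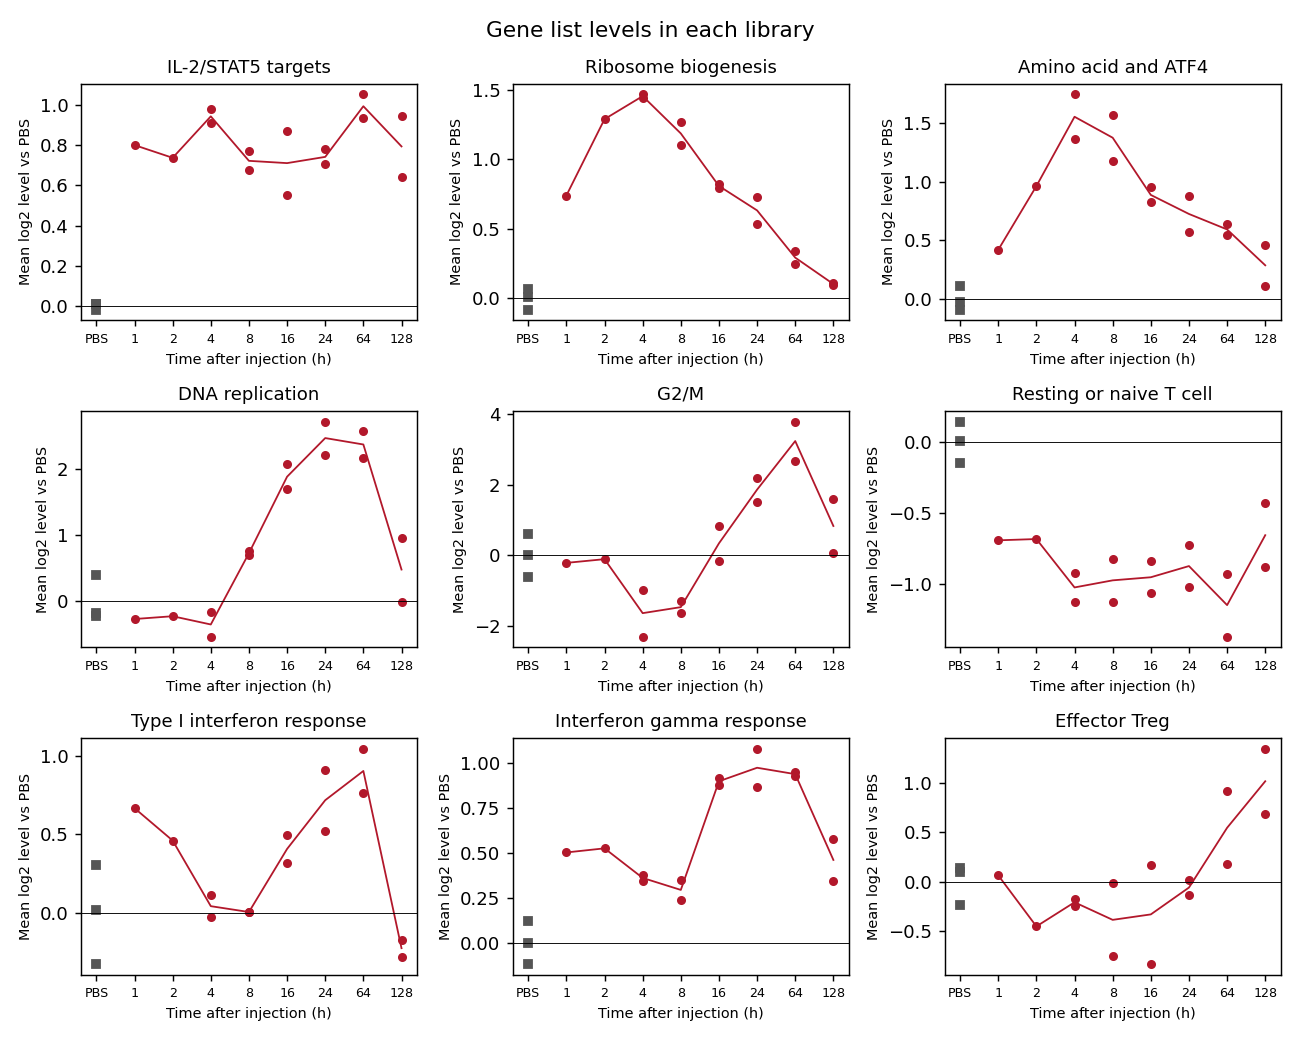
Mean log2 level of 9 gene lists relative to the PBS mean (vertical axis) against hours after IL2_JES6 injection (horizontal axis, evenly spaced times), with red points for injected libraries, a red line for their mean and grey squares for the 3 PBS libraries. The highest means stand at 4 h for ribosome biogenesis, 24 h for DNA replication and 64 h for G2/M.

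At 64 h all G2/M genes tested, 22 of 42 type I interferon response genes and the granzymes Gzma and Gzmb were higher than in PBS. All 40 G2/M genes tested rose, 40 adjusted over the list alone (mean log2 change 3.26, camera adjusted p = 1.42e-17, adjusted p = 0.226 with an estimated correlation), and 25 did so without 64 h replicate 1. The survivin gene Birc5 (197 ± 83.7 against 12.2 ± 5.87 CPM, 4.02 ± 0.77), the kinetochore gene Nuf2 (4.02 ± 0.80), Mki67 (2.92 ± 0.48) and the mitotic kinases Ttk (3.98 ± 0.84) and Aurkb (3.96 ± 0.88) rose, the kinases with adjusted p of 0.0688 and 0.0586 without 64 h replicate 1. Without that library Nuf2, Ttk and Aurkb stood at 3.05, 2.89 and 2.92. Without 64 h replicate 2 Nuf2, Ttk and Aurkb stood at 4.63, 4.63 and 4.59. Without the 128 h PBS library Nuf2 and Aurkb stood at 4.82 and 4.65, and Ttk at 5.21 and 3.39 without 2 h PBS replicates 1 and 2. In the type I interferon response list 22 of 42 genes rose, and 24 rose and 1 fell adjusted over the list alone (mean 0.86, adjusted p = 1.21e-08, adjusted p = 0.248 with an estimated correlation). Isg15 (2.24 ± 0.26), Oas2 (2.08 ± 0.40), Isg20 (2.04 ± 0.17) and Oasl2 (1.97 ± 0.33), all antiviral effectors, rose.

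Gzmb reached 1997 ± 454 CPM at 64 h (5.77 ± 0.58, adjusted p = 5.4e-05), granzyme A, Gzma, 132 ± 15.8 from 0.702 ± 1.06 CPM (7.57 ± 0.76) and the inflammasome gene Nlrp6 41.9 ± 20.8 from 0.414 ± 0.43 CPM (6.55 ± 0.75). Ifitm3 stood at 1002 ± 62.9 CPM (7.31 ± 0.37), Ifitm2 at 266 ± 28.2 against 2.06 ± 0.63 (128-fold) and Tgm2 at 479 ± 354 (7.21 ± 0.51). Ifitm1 held 1056 counts against 3 in PBS, a ratio of 593 (95% counting interval 202.5 to 2882), and 1155 without 2 h PBS replicate 2 (206.8 to 45660). Without the 128 h PBS library Gzma held 1 count in PBS, a ratio of 1507 (270 to 59560), and without 2 h PBS replicate 2 it stood at 6.97. Nlrp6 stood at 5.93 without 64 h replicate 1, and without 2 h PBS replicate 2 it held 2 counts in PBS, a ratio of 227.5 (62.6 to 1885). Tgm2 stood at 7.82 and 6.17 without 64 h replicates 1 and 2. The largest falls were those of Cd83, a surface protein of activated lymphocytes (12.7 ± 4.80 against 242 ± 54.8 CPM, -4.25 ± 0.27), Rgs16 (-4.13 ± 0.53), St8sia6 (-4.07 ± 0.62) and the chemokine receptor Cxcr4 (-4.01 ± 0.92, adjusted p = 0.0038, and -3.26 with 0.0542 without 64 h replicate 2). Without 64 h replicate 1 Cxcr4 held 2 counts at 64 h, a PBS to injected ratio of 52.8 (14.5 to 437.5). Its PBS mean of 21.4 ± 15.9 CPM rests mostly on the 2 h PBS libraries, at 25.1 and 35.2 CPM. The 128 h PBS library held 4.05 CPM and the 64 h libraries 2.18 and 0.418 CPM.

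Among the 30 IL-2/STAT5 targets 18 rose and 1 fell at 64 h, 18 and 1 adjusted over the list alone (adjusted p = 1.06e-07, adjusted p = 0.0898 with an estimated correlation), with Socs2 at 2.80 ± 0.13 and the cytokine oncostatin M, Osm, at 2.46 ± 0.20. Of 24 resting or naive T cell genes 17 fell and 1 rose, 18 and 1 adjusted over the list alone (adjusted p = 3.35e-08, adjusted p = 0.247 with an estimated correlation), with Bcl6 at -3.57 ± 0.50, Tcf7 at -2.65 ± 0.20, Il7r at -2.64 ± 0.27 and Tdrp at -2.84 ± 0.79 (adjusted p = 0.012, 0.142 without 64 h replicate 1 and 0.0506 without 64 h replicate 2). The chemokine receptor Ccr7, which guides cells into lymphoid tissue, fell by 1.02 ± 0.21. Of 25 cholesterol synthesis genes 17 rose, 19 adjusted over the list alone (adjusted p = 6.98e-08, adjusted p = 0.201 with an estimated correlation), and 8 without 64 h replicate 1. Sqle (1.78 ± 0.26), Fdps (1.70 ± 0.31), Cyp51 (2.82-fold) and the cholesterol carrier Stard4 (1.56 ± 0.23) rose.

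In the effector Treg list 7 of 32 genes rose and 3 fell at 64 h, 7 and 3 adjusted over the list alone (mean log2 change 0.55, camera adjusted p = 0.0447, adjusted p = 0.763 with an estimated correlation). That list had adjusted p of 0.462 without 64 h replicate 1, 0.133 without 2 h PBS replicate 1, 0.0501 without 8 h replicate 2 and 0.0516 and 0.0518 without 4 h replicates 1 and 2. Ccr5, a receptor for inflammatory chemokines, rose (61.7 ± 29.4 against 9.79 ± 2.76 CPM, 2.66 ± 0.47, adjusted p = 0.00057, and 2.07 without 64 h replicate 1). Rorc, a transcription factor of T cells that make interleukin-17, fell (0.901 ± 0.684 against 6.50 ± 3.20 CPM, -2.81 ± 0.93, adjusted p = 0.0325). Rorc held 2 counts at 64 h without 64 h replicate 1, a PBS to injected ratio of 15.9 (95% counting interval 4.29 to 132.6, adjusted p = 0.0886), and without 64 h replicate 2 it stood at -2.19 (adjusted p = 0.211). Its adjusted p was 0.0662 and 0.0919 without 2 h PBS replicates 1 and 2 and 0.0602 with thinned libraries.

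Among 27 chemokine receptor and egress genes 3 rose and 8 fell at 64 h, 4 and 10 adjusted over the list alone, and the list was not called (adjusted p = 0.341). The falls numbered 2 without 64 h replicate 2 and 5 without 2 h PBS replicate 1. Beside Cxcr4, the receptors Ccr3 (-2.78 ± 0.82, adjusted p = 0.0207) and Ccr6 (-2.28 ± 0.72, adjusted p = 0.0332) fell. Ccr3 stood at -4.82 without 64 h replicate 1 and -1.95 without 64 h replicate 2 (adjusted p = 0.146 without the latter), and Ccr6 at -3.92 and -1.51 (adjusted p = 0.199 without the latter). Ccr3 also had 0.0545 without 2 h PBS replicate 1. Ccr6 had 0.103 without 2 h PBS replicate 2, 0.0575 and 0.0539 without 8 h replicates 1 and 2, 0.0566 with all 18 libraries and 0.174 without a low count filter.

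In the TNF receptor superfamily 7 of 22 genes rose and 5 fell at 64 h, 8 and 5 adjusted over the list alone, and the list was not called (adjusted p = 0.615). Its falls numbered 1 without 64 h replicate 1, 2 without 64 h replicate 2 and 3 without 2 h PBS replicate 1. The costimulatory receptors Tnfrsf9 (602 ± 31.2 against 182 ± 28.5 CPM, 1.72 ± 0.18), Tnfrsf4 (1.32 ± 0.17) and Tnfrsf18 (1.31 ± 0.14) rose. Tnfsf14 (-2.40 ± 0.79, adjusted p = 0.0314) stood at -3.40 and -1.79 with adjusted p of 0.0666 and 0.23 without 64 h replicates 1 and 2, and had 0.111 without the 128 h PBS library and 0.055 without 2 h PBS replicate 1. Ctla4, an inhibitory receptor of Tregs, rose by 0.64 ± 0.14. The total was 2078 genes higher and 1463 lower, and it was 1685 without 64 h replicate 1.

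At 128 h Gzmb, Gzma and the interferon-inducible membrane genes Ifitm1, Ifitm2 and Ifitm3 were still high. Gzmb stood at 1966 ± 741 CPM (5.74 ± 0.58, adjusted p = 0.0002), Gzma at 43.6 ± 4.06 (5.97 ± 0.76), Nlrp6 at 38.1 ± 5.62 (6.42 ± 0.75), Ifitm3 at 291 ± 84.3 (5.53 ± 0.35) and Ifitm2 at 95.1 ± 36.4 (5.52 ± 0.31). Ifitm1 held 679 counts against 3 in PBS, a ratio of 348 (95% counting interval 118.5 to 1691). The ratio was 166 (55.7 to 813) and 513 (174.5 to 2495) without 128 h replicates 1 and 2, and 677 (121 to 26780) without 2 h PBS replicate 2. Without the latter Nlrp6 held 2 counts in PBS, a ratio of 206 (56.6 to 1706), and Gzma stood at 5.37. Without the 128 h PBS library Gzma held 1 count in PBS, a ratio of 499 (89.1 to 19740). Cd83 fell by 3.46 ± 0.26 and Tcf7 by 1.88 ± 0.19, and Cish (690 ± 142 CPM, 1.39 ± 0.16), Il2ra (1740 ± 385 CPM, 1.13 ± 0.13) and Il2rb (1.08 ± 0.14) were still higher than PBS. With all 18 libraries Il2ra at 1.15 and Il2rb at 1.10 were not called (adjusted p of 0.0695 and 0.121).

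In the effector Treg list 9 of 32 genes rose and 1 fell at 128 h, 15 and 2 adjusted over the list alone (mean log2 change 1.04, camera adjusted p = 7.19e-07, adjusted p = 0.373 with an estimated correlation). Treg core genes rose in 11 of 25 cases and fell in 3, 13 and 3 adjusted over the list alone (adjusted p = 6.27e-06, adjusted p = 0.0898 with an estimated correlation), with 7 higher without 128 h replicate 1. The DNA replication list had a mean of 0.55 with 1 of 38 genes called by edgeR and 0 adjusted over the list alone (adjusted p = 0.0073, adjusted p = 0.707 with an estimated correlation). Its mean difference in log2 CPM was 0.48, and -0.0057 without 128 h replicate 1 (adjusted p = 0.581). Further, 8 genes were called without 128 h replicate 2 and 4 without the 128 h PBS library. Mcm5 at 0.55 ± 0.29 and Mki67 at 0.99 ± 0.49 were not called. Il10, a suppressive cytokine, stood at 15.2 ± 13.8 against 2.51 ± 0.69 CPM (2.58 ± 0.83, adjusted p = 0.0646).

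Several single-gene calls at 128 h ended when a library was left out. Leaving out a 128 h library leaves 1 at that time, so such a loss can reflect fewer samples. Ctla4 (0.52 ± 0.14, adjusted p = 0.0264) had adjusted p = 0.359 without 128 h replicate 1, 0.058 to 0.0757 without any PBS library and 0.197 with all 18 libraries. Il7r (-1.07 ± 0.25), Ccr7 (-1.15 ± 0.21) and St8sia6 (-2.83 ± 0.56) had adjusted p of 0.199, 0.0672 and 0.0926 without 128 h replicate 1, and Il7r held 89.2 and 206 CPM in 128 h replicates 1 and 2. St8sia6 stood at -3.53 without 128 h replicate 2. Without 128 h replicates 1 and 2 the adjusted p were 0.135 and 0.113 for Cxcr4 (-3.75 ± 0.90) and 0.148 and 0.0847 for Atp6v0d2 (-3.23 ± 0.77). The 128 h libraries held 1.77 and 1.36 CPM of Cxcr4 and 1.77 and 1.95 CPM of Atp6v0d2, so neither library alone set these falls. For Cxcr4 the 128 h PBS library held 4.05 CPM, against 25.1 and 35.2 CPM in the 2 h PBS libraries. Less of the Cxcr4 fall is therefore seen against PBS of the same time. The total was 776 genes higher and 346 lower. It was 300 without 128 h replicate 1, 726 without 128 h replicate 2, 663 and 701 without 2 h PBS replicates 1 and 2, and 1711 and 1743 without 8 h replicates 1 and 2. Of the 22 panel genes, Ikzf2, Icos, Klrg1, Bcl2 and Il10 were called at no time, with Bcl2 at an adjusted p of 0.0586 at 2 h.

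**Figure D3:**
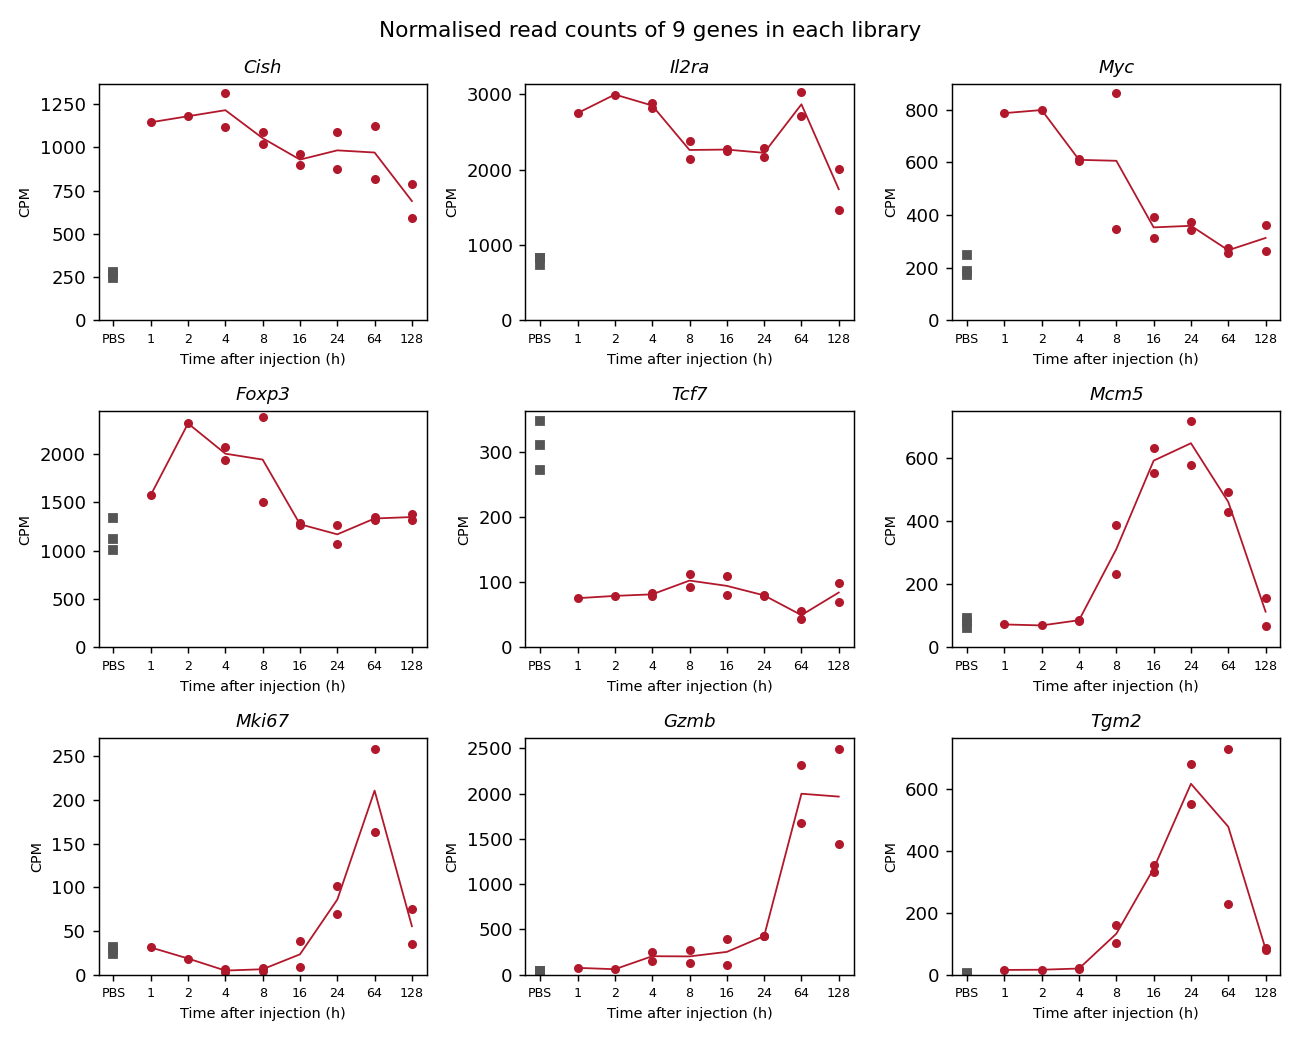
Normalised read counts in CPM (vertical axis) of 9 genes against hours after IL2_JES6 injection (horizontal axis, evenly spaced times), with red points for injected libraries, a red line for their mean and grey squares for the 3 PBS libraries. Cish and Il2ra lie above every PBS library at each time, Tcf7 below, and Gzmb reaches means of 1997 CPM at 64 h and 1966 CPM at 128 h.

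The labels span early and late times, and a direct test of 24 h against 1 h asks what changed within injected mice. DNA replication genes rose in 29 of 38 cases, 36 adjusted over the list alone (mean log2 change 2.97, camera adjusted p = 6.49e-40, adjusted p = 0.0898 with an estimated correlation), and in 12 without 24 h replicate 1. Mcm5 rose to 646 ± 98.7 in 2 libraries from 72.8 CPM in 1 (3.15 ± 0.45, adjusted p = 0.0029). Cdc6 was at least 167-fold higher, Clspn, a replication checkpoint gene, at least 61.4-fold, the centromere gene Cenph at least 32.2-fold, Gzma at least 28.6-fold and the repair glycosylase Neil3 at least 27.4-fold, each against 3 counts in the 1 h library where 0 were seen. Without 24 h replicate 1 these bounds were 20.8-fold for Cenph and 15.9-fold for Neil3, and without 24 h replicate 2 the bound was 14.6-fold for Gzma. Pask, with 3 counts at 1 h, had a ratio of 66.8 (95% counting interval 22.7 to 325). The 0 counts at 1 h came from 1 library, so these bounds do not give the rise from PBS. Neil3 held 3.59 to 6.36 CPM in PBS and 4.48 at 2 h, Clspn 2.40 to 6.56 and 3.97, and Cenph 1.26 to 2.31 and 2.24. Cdc6 held 0.515 to 6.36 CPM in PBS and 0.345 at 2 h, and Gzma 0 to 1.93 and 0. The pseudokinase gene Trib3 (-2.37 ± 0.38), Bicd1 (-1.94 ± 0.42), the protease gene Adam19 (-1.88 ± 0.24) and the phosphatase gene Dusp6 (-1.87 ± 0.35) were lower.

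Cish, Il2ra and Socs1 had log2 changes of -0.22 ± 0.21, -0.31 ± 0.18 and 0.26 ± 0.29 between 24 h and 1 h and were not called. Adjusted p without 24 h replicate 1 were 0.0713 for Cdc6, 0.0872 for Clspn, 0.138 for Cenph, 0.0735 for Neil3, 0.128 for Dusp6, and 0.0572 for both Trib3 and Bicd1. Without 24 h replicate 2 they were 0.0902 for Gzma and 0.155 for Bicd1. Those of Gzma lay between 0.0507 and 0.0616 without either 64 h or 128 h library, 8 h replicate 1 or 2 h PBS replicate 1, and those of Cenph between 0.0526 and 0.0575 without either 64 h or 2 h PBS library. With all 18 libraries they were 0.0585 for Cdc6, 0.0505 for Clspn and 0.0889 for Gzma. Cdc6 had 0.141 without a low count filter, Gzma 0.0918 with DESeq2 and Bicd1 0.0531 with thinned libraries. The total was 208 genes higher and 62 lower. It was 48 and 169 without 24 h replicates 1 and 2 and 599 and 600 without 8 h replicates 1 and 2. The compared groups alone gave 1591 genes, DESeq2 524, no low count filter 476 and the replicate block 425.

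Between 24 h and 128 h most DNA replication genes and some interferon response genes fell, and some effector Treg genes rose. DNA replication genes fell in 28 of 38 cases, 37 adjusted over the list alone (mean log2 change -1.91, camera adjusted p = 4.36e-33, adjusted p = 0.0898 with an estimated correlation), and in 15 without 128 h replicate 2 and 12 without 24 h replicate 1. Type I interferon response genes fell in 18 of 42 cases, and 26 fell and 1 rose adjusted over the list alone (mean -0.96, adjusted p = 2.4e-14, adjusted p = 0.151 with an estimated correlation), and in 10 without 128 h replicate 2 and 7 without 24 h replicate 2. Effector Treg genes rose in 9 of 32 cases, and 14 rose and 1 fell adjusted over the list alone (mean 1.08, adjusted p = 5.12e-11, adjusted p = 0.247 with an estimated correlation), and in 3 without 128 h replicate 1 and 2 and 4 without 24 h replicates 1 and 2. Lif fell to 10.9 ± 4.10 from 111 ± 27.8 CPM (-3.35 ± 0.32, adjusted p = 1.68e-05), and Nlrp6 (5.07 ± 0.79), Ifitm1 (4.37 ± 0.69) and Frmd5 (2.58 ± 0.42) rose, Ifitm1 with adjusted p = 0.0828 in the compared groups alone. Ifitm1 stood at 3.34 and 4.96 without 128 h replicates 1 and 2 and at 3.58 and 6.31 without 24 h replicates 1 and 2. Nlrp6 stood at 4.48 without 24 h replicate 2, and without 24 h replicate 1 it held 3 counts at 24 h, a ratio of 69.8 (95% counting interval 23.7 to 340).

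The laminin receptor gene Itga7 (3.20 ± 0.55), Ptafr, the receptor for platelet-activating factor (3.17 ± 0.55), and Nhsl2 (2.69 ± 0.47) rose from 24 h to 128 h, with adjusted p of 0.0748, 0.0748 and 0.0735 without 24 h replicate 1 and, for Ptafr at 2.40, 0.0667 without 128 h replicate 2. Mcm5 fell by 2.51 ± 0.33 and Mcm8 (-3.27 ± 0.61), Dscc1 (-3.26 ± 0.68) and Cdc6 (-3.31 ± 0.77), all of DNA replication, were lower too. Without 128 h replicate 1 Mcm5 stood at -3.22, Mcm8 at -3.95, Dscc1 at -4.16 and Cdc6 at -4.38, and without 128 h replicate 2 Cdc6 stood at -2.71 and Itga7 at 2.60. Without 24 h replicate 1 and without 128 h replicate 2 the adjusted p were 0.0592 and 0.0877 for Mcm8, 0.106 and 0.136 for Dscc1 and 0.189 and 0.225 for Cdc6. Cdc6 also had 0.0832 without 24 h replicate 2, 0.0532 without 128 h replicate 1, 0.0531 and 0.0502 without 8 h replicates 1 and 2, 0.0965 with all 18 libraries and 0.239 without a low count filter. Il7r at 1.00 ± 0.27 (adjusted p = 0.0436) stood at 0.28 without 128 h replicate 2, and had adjusted p of 0.0544 to 0.722 without that or any PBS, 4 h, 16 h, 24 h or 64 h library and 0.279 with the compared groups alone. Ccr7 at -0.89 ± 0.23 (adjusted p = 0.0296) had 0.0888 to 0.22 without any 24 h or 128 h library and 0.0901 with all 18 libraries. The total was 214 genes higher and 297 lower. It was 106 and 198 without 24 h replicates 1 and 2, 303 and 161 without 128 h replicates 1 and 2, and 941 and 946 without 8 h replicates 1 and 2. DESeq2 called 781, and the compared groups alone gave 896.

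Markers of other cell types moved in both directions. Of 15 B cell markers tested 2 rose and 2 fell at 64 h, 2 and 2 adjusted over the list alone (adjusted p = 0.728 for the list). The immunoglobulin gene Ighm lay at 591.5 to 999 CPM in the injected libraries of 1 h to 8 h, below every PBS library (1239 to 1560 CPM). At 64 h it stood at 2067 ± 344 against 1436 ± 172 CPM (0.53 ± 0.17, adjusted p = 0.0305). Cd79b, at 19.3 ± 5.76 CPM in PBS, stood at 1.11 ± 0.32 at 64 h. Both calls ended without 64 h replicate 1 (adjusted p 0.341 and 0.279) or 2 h PBS replicate 2 (0.0543 and 0.0703), that of Ighm also without 2 h PBS replicate 1 (0.126) and with all 18 libraries (0.225). The class II chaperone gene Cd74 (-1.17 ± 0.29) had adjusted p of 0.056 and 0.0525 without 64 h replicates 1 and 2, and Fcmr (-2.51 ± 0.83) had 0.112 and 0.192, and stood at -1.48 with 0.22 without 2 h PBS replicate 2. The B cell list was lower at 4 h with 2 of 15 genes called, 2 adjusted over the list alone (adjusted p = 0.0465, adjusted p = 0.179 with an estimated correlation). Its adjusted p lay between 0.053 and 0.0999 without either 8 h or 24 h library, 4 h replicate 1, 64 h replicate 2, 128 h replicate 1 or 2 h PBS replicate 2, and was 0.0993 without a low count filter.

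Of 17 myeloid markers edgeR called Ly6c2 higher (1.61 ± 0.42) and Zbtb46 lower (-1.52 ± 0.44) at 24 h, 1 and 1 adjusted over the list alone (adjusted p = 0.408 for the list). Adjusted p without 24 h replicates 1 and 2 were 0.196 for Ly6c2 and 0.278 for Zbtb46 respectively, and those without 2 h PBS replicate 1 were 0.0536 and 0.0597, with 0.0659 for Zbtb46 without 2 h PBS replicate 2. In thinned libraries they were 0.264 and 0.216, and Zbtb46 stood at -2.23 without 24 h replicate 1. Ly6c2 was also higher at 64 h (3.93 ± 0.41, adjusted p = 1.44e-06) and 128 h (3.49 ± 0.41, adjusted p = 1.625e-05), with 40.7 and 43.0 CPM and 32.7 and 28.8 CPM in their libraries against 2.33 to 3.28 in PBS, times chosen after its values were seen. Among 7 NK cell markers Gzma rose and the chemokine gene Ccl5, also in the effector Treg list, fell (1.89 ± 2.08 against 23.5 ± 7.85 CPM, -3.60 ± 0.68, with 3.36 and 0.418 CPM in 64 h replicates 1 and 2, and -2.76 without 64 h replicate 2) at 64 h, 1 and 1 adjusted over the list alone (adjusted p = 0.863 for the list). Without 64 h replicate 1 Ccl5 held 2 counts at 64 h, a PBS to injected ratio of 55.8 (95% counting interval 15.4 to 462.5). Of 5 CD8 T cell markers Ccl5 and Crtam fell at 64 h, 2 adjusted over the list alone (adjusted p = 0.162 for the list). Crtam held 1 count at 64 h against 52 in PBS, a PBS to injected ratio of 30.8 (95% counting interval 5.3 to 1241). Without 64 h replicate 2 the ratio was 15.8 (2.72 to 637.7), and without 64 h replicate 1, with 0 counts left at 64 h, Crtam was lower by at least 5-fold. Its adjusted p of 0.0252 was 0.0943 and 0.16 without 64 h replicates 1 and 2, 0.0666 without the 128 h PBS library and 0.0528 without 2 h PBS replicate 1.

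Of 4 erythroid markers tested at 4 h the transferrin receptor gene Tfrc rose (2.05 ± 0.45, adjusted p = 0.109 without a low count filter) and Bpgm fell (-0.96 ± 0.26, adjusted p = 0.0146), 1 and 1 adjusted over the list alone, and Bpgm had adjusted p = 0.243 without 4 h replicate 1, 0.0515 without 2 h PBS replicate 1 and 0.0548 with thinned libraries. Of 2 platelet markers the integrin gene Itgb3 fell at 2 h (-1.80 ± 0.34), 1 adjusted over the list alone. Of 3 conventional T cell cytokine genes the inflammatory cytokine Tnf rose (1.02 ± 0.20) and the CD40 ligand gene Cd40lg fell (-1.17 ± 0.30, adjusted p = 0.0071) at 64 h, 1 and 1 adjusted over the list alone, and Cd40lg had adjusted p of 0.051 and 0.0761 without 64 h replicates 1 and 2. These 3 lists held too few tested genes for the list test.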

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

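The results below are differences between times within injected mice, each tested directly, and the lists were fixed before the data were examined. The weighing of patterns is given under the other observations.

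From 1 h to 24 h 270 genes differed. Mcm5 rose by 3.15 (adjusted p = 0.0029), and the lists for DNA replication (mean log2 change 2.97), G2/M (2.23), cholesterol synthesis (0.58), oxidative phosphorylation (0.55), class I antigen presentation (0.49), the interferon gamma response (0.49), amino acids and ATF4 (0.37), the unfolded protein response (0.36), glycolysis (0.36) and ribosomal proteins (0.24) were higher at 24 h. Cytokine signalling brakes were lower (-0.45, adjusted p = 0.0488). With an estimated correlation no list was called, and the lowest adjusted p was 0.0898. Without 24 h replicates 1 and 2 the count was 48 and 169 genes, and without 8 h replicates 1 and 2 it was 599 and 600. Without 24 h replicate 1 amino acids and ATF4 had adjusted p of 0.212 and the brakes 0.178. The brakes had 0.0518 to 0.0548 without any 4 h, 16 h or 128 h library or 64 h replicate 2, 0.129 without a low count filter and 0.934 with all 18 libraries. Ribosomal proteins had 0.171 with the replicate block.

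From 24 h to 128 h 511 genes differed. Il7r stood at 1.00, Ccr7 at -0.89 and Mcm5 at -2.51. The lists for effector Tregs (1.08), immediate early genes (0.36), chemokine receptors (0.32) and the T cell receptor complex (0.29) were higher at 128 h. Lower were DNA replication (-1.91), the type I interferon response (-0.96), G2/M (-0.88), ribosome biogenesis (-0.53), the interferon gamma response (-0.52), amino acids and ATF4 (-0.41), ribosomal proteins (-0.26), oxidative phosphorylation (-0.26) and the unfolded protein response (-0.24). Here too no list was called with an estimated correlation, the lowest adjusted p being 0.0898. The count was 106 and 198 without 24 h replicates 1 and 2, 303 and 161 without 128 h replicates 1 and 2, and 941 and 946 without 8 h replicates 1 and 2. Il7r had adjusted p of 0.0544 to 0.722 without any PBS, 4 h, 16 h, 24 h or 64 h library or 128 h replicate 2, and Ccr7 0.0888 to 0.22 without any 24 h or 128 h library. With the compared groups alone Il7r had 0.279, and with all 18 libraries Ccr7 had 0.0901. Without 128 h replicate 2 G2/M had 0.401, the unfolded protein response 0.0615 and immediate early genes 0.0598. Immediate early genes also had 0.106 without 24 h replicate 1, chemokine receptors 0.126 without 24 h replicate 2 and ribosomal proteins 0.251 without 128 h replicate 1. With all 18 libraries the calls of oxidative phosphorylation and ribosomal proteins (both 0.358), the unfolded protein response (0.423), the T cell receptor complex (0.21) and chemokine receptors (0.083) also ended.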

How the results depend on the processing

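The fit of all 18 libraries was the planned one and became an alternative after the data were seen, when 17 were kept. The other alternatives were chosen before. The cause of each change below was not tested, except that a 2-fold minimum adds a requirement and that leaving out a library leaves fewer samples.

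For counts of genes called, DESeq2 gave 458 at 1 h, 524 for 24 h against 1 h, 781 for 128 h against 24 h and 19 for PBS. Without a low count filter there were 457 at 1 h, 476 for 24 h against 1 h and 30 for PBS. The replicate block gave 425 for 24 h against 1 h, and thinning gave 4 for PBS. The compared groups alone gave 1705 at 8 h, 1591 for 24 h against 1 h, 896 for 128 h against 24 h and 8 for PBS. A minimum 2-fold change left 1027 at 4 h, 1316 at 8 h, 733 at 16 h, 842 at 24 h, 1924 at 64 h, 573 at 128 h and 319 for 128 h against 24 h.

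With each library left out in turn the counts ran from 186 to 509 at 1 h, 1156 to 2808 at 4 h, 1710 to 3583 at 8 h, 861 to 2466 at 16 h, 681 to 2493 at 24 h, 1685 to 4274 at 64 h and 300 to 1743 at 128 h. They ran from 48 to 600 for 24 h against 1 h, 106 to 946 for 128 h against 24 h and 0 to 11 for PBS, where edgeR called 2 with 735 at an unadjusted p under 0.05. The counts at 2 h and at any time stayed within 1.5 times under every alternative run.

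Of 270 list tests 140 were called, and 2 with an estimated correlation, both ribosome biogenesis (2 h and 4 h). With all 18 libraries, which include the failed one, 6 lists reversed relative to the other genes, with mean log2 CPM differences at 1 h of Treg core (-4.28), ribosome biogenesis (-3.27), amino acids and ATF4 (-3.06), type I (-3.36) and gamma interferon (-3.81), and for 24 h against 1 h cytokine brakes (3.20). IL-2/STAT5 targets (-3.14) and cytokine brakes (-2.78) at 1 h also had means below 0. All of these means draw on the failed 1 h library, so they do not show which way the lists moved. Leaving out single libraries, ribosomal proteins at 8 h ran from -0.0403 to 0.91 and DNA replication at 128 h from -0.0057 to 0.97.

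Of 284 named gene results none reversed. The calls lost were 21 with all 18 libraries, 11 without the filter, 10 thinned, 5 with the compared groups alone, 3 with DESeq2, 1 with RLE and 3 to 22 with a library left out. In simulated data 39.4% of genes changed by 1 log2 unit were recovered at 4 h, with 2 libraries, and 21.6% at 1 h, with 1. Recovery was not split by count or depth, so these shares do not show what depth limits.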

Other observations

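The tests of cycling cells at 4 h and 8 h and of gamma delta T cells from 2 h onward were chosen after the results were seen.

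G2/M genes were lower at 4 h and 8 h than in PBS. With every library thinned to 1483975 counts the mean difference of the list in log2 CPM was -1.30 at 4 h (adjusted p = 9.34e-07) and -1.04 at 8 h (adjusted p = 0.00098), which argues against depth as the whole cause. Before thinning neither list call held with an estimated correlation (adjusted p = 0.422 at 4 h and 0.636 at 8 h). A loss of cycling cells may underlie the pattern and stays open at 4 h: the DNA replication list, which such cells also express, had a mean difference of -0.35 (adjusted p = 0.235), against -1.63 for G2/M, neither above 0 nor below the -0.5 that was named. At 8 h it had 0.72 (adjusted p = 2.02e-05, 0.49 with an estimated correlation), with both libraries above every PBS library, which argues against such a loss as the only change, though a loss beside a rise in other cells stays open.

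The constant genes of the T cell receptor gamma locus, Trgc1 to Trgc4, summed to 66.4 to 188 CPM in the 14 injected libraries and to 5.59 to 22.9 in the 3 PBS libraries, so all 14 lay above every PBS library. These genes were picked because they were higher, so the exact permutation p of 0.00147 over 680 splits, the smallest they can give, tests no explanation. Gamma delta T cells, which a sort for TCRB and CD4 would remove, would bring the delta constant gene Trdc, but from 2 h to 128 h its highest log2 change plus 2 SE was 1.25, below the lowest Trgc1 change of 2.22, which argues against such cells at these times. At 1 h, in 1 library, Trdc came to 10.7% of the gamma sum, above the 10% named beforehand, but the rise that was also named was not seen: Trdc stood at 7.13 against 6.27 ± 3.02 CPM (log2 change 0.18 ± 0.81, adjusted p = 0.975), while the gamma sum stood at 66.4 against 13.8 ± 8.7. The wide error keeps such cells open there, and transcription of the locus after injection and reads shared between these paralogs stay open as well.

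The 8 h replicate 2 library detected 15716 genes, and 8 h replicate 1 thinned to its total detected 17014, which argues against lower depth as the whole cause. The lowest other thinned library detected 16097. No biological explanation was tested, since both libraries belong to 1 group.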
